A study of Homo sapiens with 3 samples.

How the data were processed

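Total RNA of 3 human nuclear transfer samples was isolated with a PicoPure kit, amplified in 2 rounds and labelled with biotin, per the labels' protocols, and hybridised to arrays of 1 chip. The groups were taken from the labels: 2 SCNT samples with an enucleated host oocyte and 1 hybrid sample whose host oocyte kept its genome. The treatment text shared by all samples mentions enucleation for the hybrid too, and the source name and host cell type of that sample were followed instead. The table holds 29377 probes with values, and 24008 blank lines were left out.

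The deposited values are probe intensity on a linear scale, exported with GenomeStudio 2009.1, per the submitters' processing notes. The background had already been subtracted from the deposited intensity, since 32.9%, 34.0% and 27.7% of the values on SCNT 1, SCNT 2 and the hybrid array lie below 0. The background method and the annotation build are not given in the sources used here. Each intensity has a deposited detection p-value, per the file headers, whose steps fit 290 negative control probes. A second deposited table by the authors holds the same intensity values multiplied by 1 factor per array (1.13, 1.60 and 0.672), which gives all arrays the same mean. It is on a linear scale with no centring, and its column medians are 18.7, 23.0 and 23.5.

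The signals were normalized with neqc of limma 3.58.1 in R 4.3.3, with the background estimated from the detection p-values, an offset of 16, quantile normalization and log2. Probe names came from the platform's annotation table, where 27988 probes had 1 gene symbol, 0 had several and 1389 had none. Of the named probes 27819 matched a gene in the RefSeq table of assembly GRCh38.p14, used for symbols alone, and 0 symbols changed. Probes counted as detected at a detection p under 0.01. A gene was kept where a probe was detected on at least 1 array, which left 9954 genes of 19347, and the probe with the highest mean log2 value stood for it. Of 2033 genes with several detected probes, 639 had probes that differed in sign. Sex-linked marker genes were left out of every table.

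SCNT was compared with hybrid by limma (lmFit and eBayes, Benjamini-Hochberg adjustment). Both SCNT arrays give 1 residual degree of freedom, so the hybrid array is assumed to vary like the SCNT arrays. The prior had 2.59 degrees of freedom. No batch term was fitted, since all arrays share a chip. Genes were also counted by size where each SCNT array differed from the hybrid array by at least 1 on the log2 scale in the same direction. The 18 gene lists, fixed before the data were examined, share no gene. They were tested with limma's camera at a preset correlation of 0.01, and set against 10000 random lists of the same size drawn within 20 bins of mean expression. A gene undetected on 1 of both SCNT arrays entered the fit at its measured value there. A gene undetected on all arrays of one side and detected on all of the other is given as at least N-fold apart. The bound sets the other side's mean against, per array, the higher of the lowest signal among detected probes (log2 7.00, 7.76 and 5.93 on SCNT 1, SCNT 2 and the hybrid array) and the gene's own signal, all after normalization, so the bounds are lower than the fitted differences.

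Genes were named by a rule fixed before the data were examined. It takes the 12 highest and the 12 lowest genes past the adjusted test with at least 2-fold in each SCNT array, filled, where too few pass, by the largest of the smaller of both differences, which was the case for all of them. It adds up to 4 detected members of each list with the largest absolute difference, and POU5F1, NANOG, GDF9, ZP3, VIM, COL1A1, ACTB and GAPDH. Genes named outside the rule are marked as such.

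The tests were run on simulated data for the same comparison, 20 times with 9954 genes, of which 200 had known changes, with the spread drawn from the fitted prior. Limma called 0 of 1324 genes changed by 2 (log2), 0 of 1307 changed by 4 and 0 of 1369 changed by 6 at adjusted p under 0.05. At an unadjusted p under 0.05 it found 30.0%, 85.0% and 95.0% of them in the right direction. Camera called a list shifted by 2 in 20 of 20 runs and 0 of 340 unshifted lists, with genes simulated as independent. Alternatives covered the background, scaling, detection filter, probe choice, prior and list test, and each SCNT array left out. They were computed with 1 choice changed at a time, with these exceptions. The normexp alternative changes the background method and the offset together. Leaving out the background correction also puts a floor of 1 in place of the offset. The authors' scaled values replace the background correction, the floor and the scaling together. Sequence positions, genotypes and the scanner images were not used here.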

Results

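Gene expression was measured with BeadChip arrays on 3 human samples made by moving an adult somatic cell genome into a mature (metaphase II) oocyte. In 2 samples, called SCNT here for somatic cell nuclear transfer, the oocyte's own genome had been removed. In 1 sample, called the hybrid, it had been left in place beside the somatic genome. All were collected at the cleavage stage. The series asks whether the human oocyte can reset a somatic genome when its own genome is absent, so the comparison is SCNT minus hybrid. The labels do not say whether the samples share donors or hold 1 embryo each, so no p-value below measures the spread between donors. Limma's p-values for genes rest on the spread between both SCNT samples, moderated across genes. Those of camera with a preset correlation rest on the spread across genes on these 3 arrays. Of 29377 probes, 8437 (28.7%) were detected on SCNT 1, 6825 (23.2%) on SCNT 2 and 11698 (39.8%) on the hybrid array. The mean signal before scaling was 586, 412 and 984 in the same order, and the number of arrays limits the precision of every value below.

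On balance, transcripts stored in the oocyte had higher values on both SCNT arrays than on the hybrid array, and genes of the trophectoderm and of oxidative phosphorylation had lower ones. These 3 lists passed limma's camera test with a preset correlation, and none did with an estimated one (adjusted p = 0.924 for each). The latter test had 1 residual degree of freedom, on which a list could hardly pass. Losing the call there does not by itself show that correlation between genes accounts for it. The estimates were -0.026 for the trophectoderm and -0.013 for the oxidative phosphorylation list, below the preset 0.01. A higher correlation therefore does not account for the calls these lists lost. For the maternal list, with an estimate of 0.52, that stays open. The median gene of the oocyte maternal list differed by 3.33 (log2, SCNT minus hybrid), that of the trophectoderm list by -3.31 and that of the oxidative phosphorylation list by -1.32. The maternal list was graded, with SCNT 2 between SCNT 1 and the hybrid array for 24 of its 30 detected genes. Of 28 genes on the array that mark activation of the embryonic genome, 19 were detected on all 3 arrays, and the list median was 0.05. The samples include no oocyte before transfer and no donor cell. Detection therefore does not separate new transcription from RNA stored in the oocyte. No single gene of 9954 passed the adjusted test, so the gene values below are measurements on these arrays and not calls. For 19 of the genes named by rule, 1 of the SCNT arrays was below detection and entered at its background value, so their differences and SEs rest partly on background: KRT8, S100A6, ZFP42, TFCP2L1, HAS2, STAR, CORO1A, MX1, IFITM3, BAX, TET1, HDAC3, PHLDA2, NOB1, UQCRC1, NDUFB7, HMOX1, PGK1 and NANOG.

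The oocyte maternal list holds genes whose transcripts are laid down during oocyte growth. Of its 30 detected members, 21 were at least 2-fold higher on each SCNT array than on the hybrid array and 1 was at least 2-fold lower on each. OOSP2, which encodes an oocyte-secreted protein, had a log2 level of 12.83 ± 0.99 (SD, n = 2) on the SCNT arrays and was not detected on the hybrid array, a difference of at least 120-fold. WEE2, the oocyte kinase that holds meiotic arrest, had a level of 15.03 ± 0.12 (SD, n = 2) against 8.64 on the hybrid array, a log2 difference of 6.39 (SE 0.75). BTG4, which recruits the deadenylase that clears maternal mRNA, was at least 17.2-fold higher, and TLE6, a member of the subcortical maternal complex, differed by 4.88 (SE 1.35). GDF9, the oocyte growth factor, differed by 3.58 (SE 1.39). NLRP7, a maternal-effect gene, was the member that was lower, by -3.26 (SE 1.10). It lies outside the gene selection rule and was named after its value was seen. ZP3, a zona pellucida protein gene, was on the array and not detected on any of the 3.

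The maternal list stood apart from the other genes in limma's camera test with a preset correlation of 0.01 (adjusted p = 1.39e-07 over 18 lists), and its median lay above those of 10000 random lists matched on expression, while the trophectoderm and oxidative phosphorylation medians lay below theirs. Of the lists that did not pass, heat shock and stress (percentile 0.100), housekeeping (0.940), histone (2.11) and splicing (2.22) also lay below the 2.5 percentile of their random lists, and p53 was at 97.4. These percentiles are unadjusted and use fitted values, undetected genes included. With an estimated correlation, 0.52 for the maternal list, limma's camera gave that list adjusted p = 0.924 on 1 residual degree of freedom. The list median against the hybrid array was 4.36 for SCNT 1 and 2.07 for SCNT 2, and 26 of the 30 members had the higher value on SCNT 1 of the SCNT arrays, with 29 detected there and 23 on SCNT 2. SCNT 2 was the middle array for 24 of the 30 members (80%), against 36.8% of all genes. It was also in the middle for 8 of 13 trophectoderm genes (61.5%) and 21 of 56 oxidative phosphorylation genes (37.5%). With genes undetected on one side set to their bound, the maternal median was 2.51. This includes bounds for the 7 members detected on 1 SCNT array alone, with the other SCNT array at its measured value. The median was 2.39 with those 7 set to 0. Adjusted over the list alone, 2 members passed limma's test, OOSP2 and WEE2 (adjusted p = 0.0417 for each). Over all genes tested, 0 passed.

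**Figure D1:**
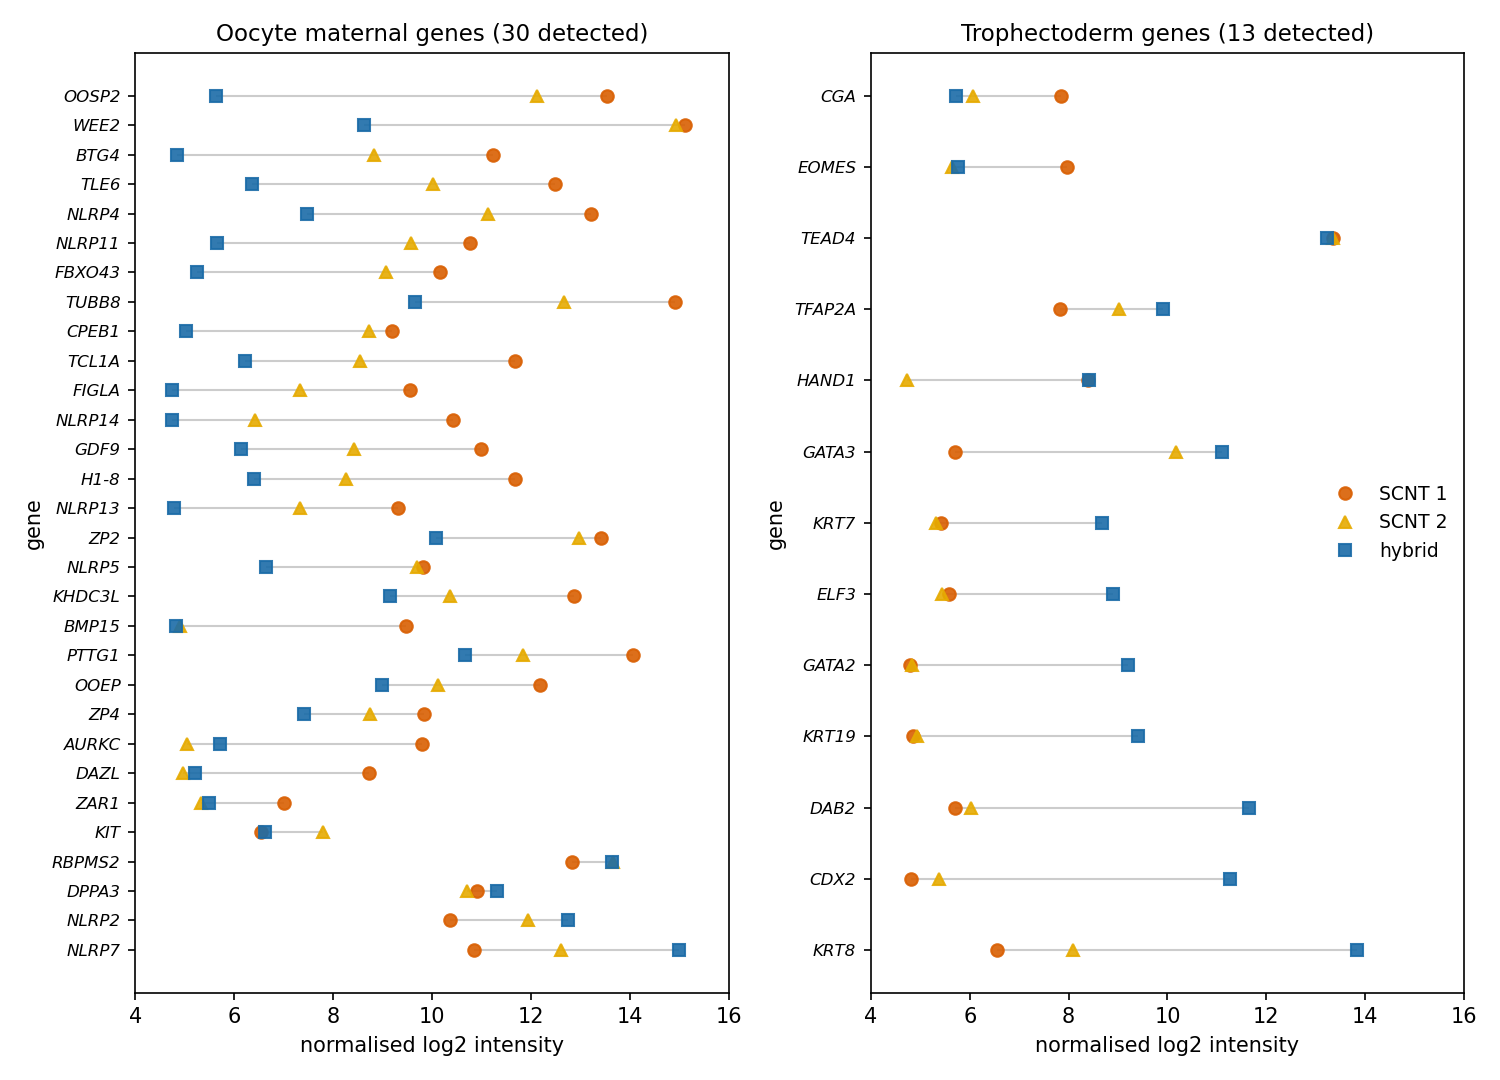
Normalised log2 intensity (x axis) of each detected gene of the oocyte maternal list and of the trophectoderm list (y axis), with 1 point per array and a grey line spanning the 3 arrays. OOSP2 and WEE2 have both SCNT points far to the right of the hybrid point, and KRT8 and CDX2 have both far to the left.

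Trophectoderm genes mark the outer layer of the blastocyst. Of 13 detected members, 11 were detected on the hybrid array, 5 on SCNT 1 and 4 on SCNT 2. In all, 7 were at least 2-fold lower on each SCNT array and 0 were at least 2-fold higher on each. KRT8, an epithelial keratin, was at 13.83 on the hybrid array and at 8.09 on SCNT 2, and it was not detected on SCNT 1. Its log2 difference, with SCNT 1 at its background value, was -6.50 (SE 1.02). CDX2, the trophectoderm transcription factor, was not detected on either SCNT array and was at least 14.8-fold lower there. The endocytic adaptor DAB2 was at least 19.3-fold lower and the keratin KRT19 at least 4.04-fold lower. TEAD4, which acts upstream of CDX2, was at 13.34, 13.35 and 13.22 on SCNT 1, SCNT 2 and the hybrid array. It was named after its values were seen. Limma's camera gave adjusted p = 0.000274 for this list with the preset correlation and adjusted p = 0.924 with an estimated one, on 1 residual degree of freedom. Adjusted over the list alone, 7 members passed limma's test, and over all genes 0 did. Of those 7, 6 were undetected on both SCNT arrays, so their p-values rest on background values there and not on the bounds. The median with undetected genes at their bound was -1.82.

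Pluripotency genes went both ways, with a list median of -0.47 over 18 detected members (limma camera, adjusted p = 0.599). On each SCNT array 6 were at least 2-fold lower and 1 was at least 2-fold higher. POU5F1, which encodes OCT4, was at 10.64 on the hybrid array and not detected on either SCNT array, at least 9.58-fold lower. The gene has pseudogenes of near-identical sequence, and its probe was not checked against them. DNMT3L, a cofactor of DNA methylation, differed by -3.99 (SE 1.51). TFCP2L1 and ZFP42, markers of naive pluripotency, differed by -4.01 (SE 2.53) and -4.46 (SE 2.16). Both were detected on SCNT 2 and not on SCNT 1. NANOG was at 8.94 on SCNT 1 and 6.51 on the hybrid array, a difference of 2.43, and was not detected on SCNT 2.

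The oxidative phosphorylation list holds genes of the mitochondrial respiratory chain and ATP synthase. Of its 56 detected members, 40 had lower values on both SCNT arrays than on the hybrid array and 6 had higher values on both. By size, 26 were at least 2-fold lower on each SCNT array and 0 were at least 2-fold higher. CYC1 and UQCRC1, both of complex III, differed by -4.76 (SE 1.05) and -4.31 (SE 0.83). The ATP synthase subunit ATP5F1D differed by -4.03 (SE 0.88) and the complex I subunit NDUFB7 by -3.67 (SE 1.07). Limma's camera gave adjusted p = 1.12e-05 with the preset correlation and adjusted p = 0.924 with an estimated one, on 1 residual degree of freedom. Adjusted over the list alone, 0 members passed, as over all genes.

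Neither the housekeeping list nor the heat shock and stress list passed the test, and single members lay on both sides of the hybrid array. The glycolytic enzyme gene GAPDH differed by -4.50 (SE 0.77), the actin gene ACTB by -3.13 (SE 0.75) and the glycolytic PGK1 by -2.66 (SE 0.77), while B2M, the light chain of MHC class I, differed by 2.59 (SE 0.75). The housekeeping list had a median of -0.72 over 16 genes (limma camera, adjusted p = 0.277). The heat shock and stress list had a median of -0.95 over 23 genes, with 8 at least 2-fold lower and 1 at least 2-fold higher on each SCNT array (limma camera, adjusted p = 0.0644). HMOX1, heme oxygenase, differed by -3.69 (SE 0.89), the chaperone HSP90AB1 by -2.58 (SE 0.81) and XBP1, a factor of the unfolded protein response, by -2.19 (SE 1.13). TXNIP, an inhibitor of thioredoxin, was at least 2.38-fold lower. Among 11 alternatives, limma's fry test in place of camera included, the stress list was called lower under 6 (adjusted p from 0.000746 to 0.924 over the 11). The housekeeping list was called under 2 of 11 (0.00824 to 0.924).

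Transcripts of genome activation genes were detected in both kinds of sample, though without an oocyte or donor cell array they cannot be told from stored RNA. Of 28 list genes on the array 7 were detected on none of the arrays. Of the 21 others, 20 were detected on SCNT 1, 19 on SCNT 2 and 21 on the hybrid array. ZSCAN4, a marker of the first wave of embryonic transcription named after its value was seen, was at 11.59, 10.73 and 11.32 on SCNT 1, SCNT 2 and the hybrid array, a difference of -0.17 (SE 0.84). The homeobox gene TPRX1 differed by 4.38 (SE 1.11) and RFPL1 by 3.06 (SE 1.03). KHDC1L differed by -3.43 (SE 1.41) and the phosphatase gene ALPG by -3.13 (SE 0.98). On each SCNT array 6 members were at least 2-fold higher and 3 at least 2-fold lower (limma camera, adjusted p = 0.500). The list median was 0.58 for SCNT 1 and -0.39 for SCNT 2. Many of these genes belong to families of near-identical copies (PRAMEF, RFPL, TRIM, MBD3L), whose probes can bind more than 1 member.

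Transcripts of fibroblasts, used here as an example of a somatic donor cell because the labels name no type, were sparse. Of 39 list genes on the array, 22 were not detected on any array, COL1A1 among them. Of the 17 detected, 8 were at least 2-fold lower on each SCNT array and 0 at least 2-fold higher (median -0.79, limma camera, adjusted p = 0.115). ANXA2, a membrane-binding protein gene, differed by -6.85 on SCNT 1 and -2.91 on SCNT 2 and S100A6, a calcium-binding protein gene, by -2.90 (SE 1.03). CALD1, COL6A1 and VIM were not detected on either SCNT array and were at least 2.90-fold, 2.45-fold and 2.54-fold lower. Cumulus and granulosa genes were mostly undetected too, 12 of 18 on the array. Of the 6 detected, AMHR2, the anti-Müllerian hormone receptor gene, was at least 1.19-fold lower on the SCNT arrays, HAS2 was detected on SCNT 1 alone, at 9.62, VCAN differed by 0.51 on SCNT 1 and 2.59 on SCNT 2, and STAR by 1.09 (SE 1.00). That list had a median of 0.13 and a mean of 0.02, while limma's camera gave the direction as down (adjusted p = 0.916). Blood cell genes had a median of -0.49 over 8 detected members (limma camera, adjusted p = 0.599). LAPTM5 and HBA2 were at least 1.16-fold and 2.45-fold lower, CORO1A differed by -2.45 (SE 0.97), and CD14 was at least 3.88-fold higher.

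Genes of innate immunity and of the DNA damage response included large differences of both signs. Of 13 detected interferon response genes, 5 were at least 2-fold lower and 1 at least 2-fold higher on each SCNT array (median -0.70, limma camera, adjusted p = 0.500). ISG15, a ubiquitin-like modifier, was at least 3.45-fold lower, IFITM1 at least 2.16-fold lower, and IFITM3 differed by -3.62 (SE 0.91). MX1, an antiviral GTPase, differed by -5.43 (SE 2.93), with SCNT 1 undetected at 4.84 and the hybrid array at 13.37. Among 21 detected p53 and DNA damage genes, 7 were at least 2-fold higher and 5 at least 2-fold lower (limma camera, adjusted p = 0.648). GADD45G, a stress-induced growth arrest gene, was at least 21.4-fold lower and passed limma's test adjusted over the list alone (adjusted p = 0.0260), though not over all genes. That p rests on background values, since the gene was undetected on both SCNT arrays. The pro-apoptotic BAX differed by -4.26 (SE 0.87). RRM2B, a p53-inducible ribonucleotide reductase subunit, differed by 4.49 (SE 0.86) and the pro-apoptotic PMAIP1 by 3.24 (SE 0.75). The list median was 0.63 and its mean 0.01.

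Chromatin genes were examined because the SCNT samples, per the series' design text, were cultured for 17 h with 240 ng/ml scriptaid, an inhibitor of histone deacetylases. Whether the hybrid received it is not given in the sources used here. Of 23 detected histone genes, 4 were at least 2-fold higher and 7 at least 2-fold lower on each SCNT array (median -0.80, limma camera, adjusted p = 0.599). The linker histone gene H1-10 was at least 10.8-fold lower and H2AX at least 2.95-fold lower, H2AJ differed by -3.39 (SE 1.30), and the variant H2AZ2 differed by 4.37 (SE 0.82). Of 35 detected chromatin modifier genes, 3 were at least 2-fold higher and 8 at least 2-fold lower (median -0.31, limma camera, adjusted p = 0.599). SUV39H1, which methylates histone H3 at heterochromatin, was at least 7.03-fold lower and the DNA methyltransferase gene DNMT3A at least 1.62-fold lower. TET1, a DNA demethylation enzyme gene, differed by -2.95 (SE 1.55) and the deacetylase gene HDAC3 by -2.33 (SE 1.57). Of 13 detected imprinted genes, 3 were at least 2-fold lower and 2 at least 2-fold higher on each SCNT array (median -0.07, mean -0.86, limma camera, adjusted p = 0.599). H19, MEG3 and CDKN1C, which are expressed from the maternal allele, were detected on the hybrid array alone and were at least 4.97-fold, 6.39-fold and 2.94-fold lower on the SCNT arrays. PHLDA2 was not detected on SCNT 1, and it was at 9.71 on SCNT 2 and 9.48 on the hybrid array.

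Cell cycle genes had a median of -0.11 over 35 detected members, 2 at least 2-fold higher and 7 at least 2-fold lower (limma camera, adjusted p = 0.815). Cyclin B1, CCNB1, differed by 2.33 (SE 0.77), the replication helicase subunit MCM5 by -2.38 (SE 0.75) and the kinesin CENPE by -2.12 (SE 0.86). CCNE2 was detected on the hybrid array alone, at 6.81. That is below the lowest detected signal on either SCNT array, so no difference can be bounded. Ribosome biogenesis genes had a median of -0.28 over 31 members (limma camera, adjusted p = 0.752). RRP9 was at least 1.52-fold lower, NOB1 differed by -2.10 (SE 1.04), and GAR1 differed by 1.72 (SE 0.75) on a probe that another probe of the gene contradicts in sign. RRP1B was detected on the hybrid array alone, at 6.74, and like CCNE2 it has no bound. Splicing genes had a median of -0.32 over 39 members (limma camera, adjusted p = 0.693), and after scaling to the probes detected on all 3 arrays the cell cycle and splicing medians were 0.071 and 0.026. U2AF1, which recognises the 3' splice site, differed by -4.17 (SE 0.79) and LSM7 by -2.93 (SE 0.90), while the splicing regulator TRA2A differed by 3.05 (SE 1.42) and LSM6 by 2.02 (SE 1.01).

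**Figure D2:**
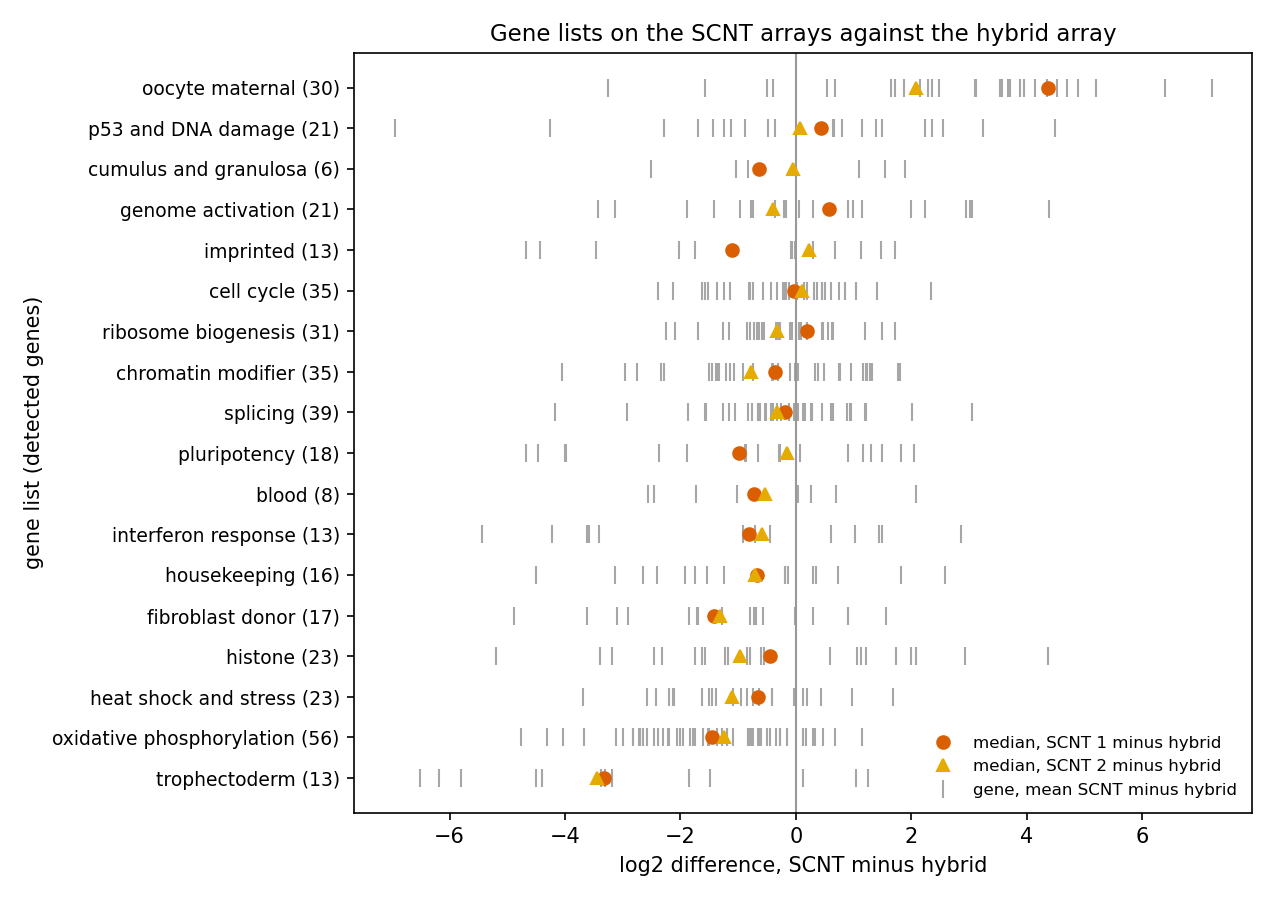
Log2 difference, SCNT minus hybrid (x axis), for the 18 gene lists (y axis, with the number of detected genes), with a grey tick per gene and a coloured marker for the list median of each SCNT array. The oocyte maternal medians lie at 4.36 and 2.07 and the trophectoderm medians at -3.32 and -3.45.

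The single genes farthest apart from the hybrid array in both SCNT arrays were measured at opposite ends of the intensity range. MEIOB, a meiotic recombination gene, was at least 184-fold higher on the SCNT arrays, the homeobox gene HOXB8 at least 82.0-fold, and LINC00623 and CMTM1 at least 52.7-fold and 30.6-fold. ADAD2, a germ cell adenosine deaminase family gene, differed by 6.71 (SE 0.77), the homeobox gene OTX2 by 6.52 (SE 0.76) and CFAP58, a cilium and sperm flagellum gene, by 6.93 (SE 0.85). RNF122, TAS1R1 and HDC differed by 6.04, 5.97 and 6.06, and OOSP2 and WEE2 complete these 12. On the lower side, the pentose phosphate enzyme gene TKT was at least 32.3-fold lower, the mitochondrial ribosomal protein gene MRPL23 at least 48.6-fold, and ECHS1, of mitochondrial fatty acid oxidation, at least 49.5-fold. SAPCD2 was at least 50.7-fold lower, the transcription factor gene CEBPA at least 23.9-fold, UCKL1 at least 18.9-fold and the growth factor gene MDK at least 17.2-fold. CD320, the receptor for transcobalamin, and the zinc transporter gene SLC30A2 were each at least 13.7-fold lower, and GADD45G, CDX2 and KRT8 complete these 12.

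**Figure D3:**
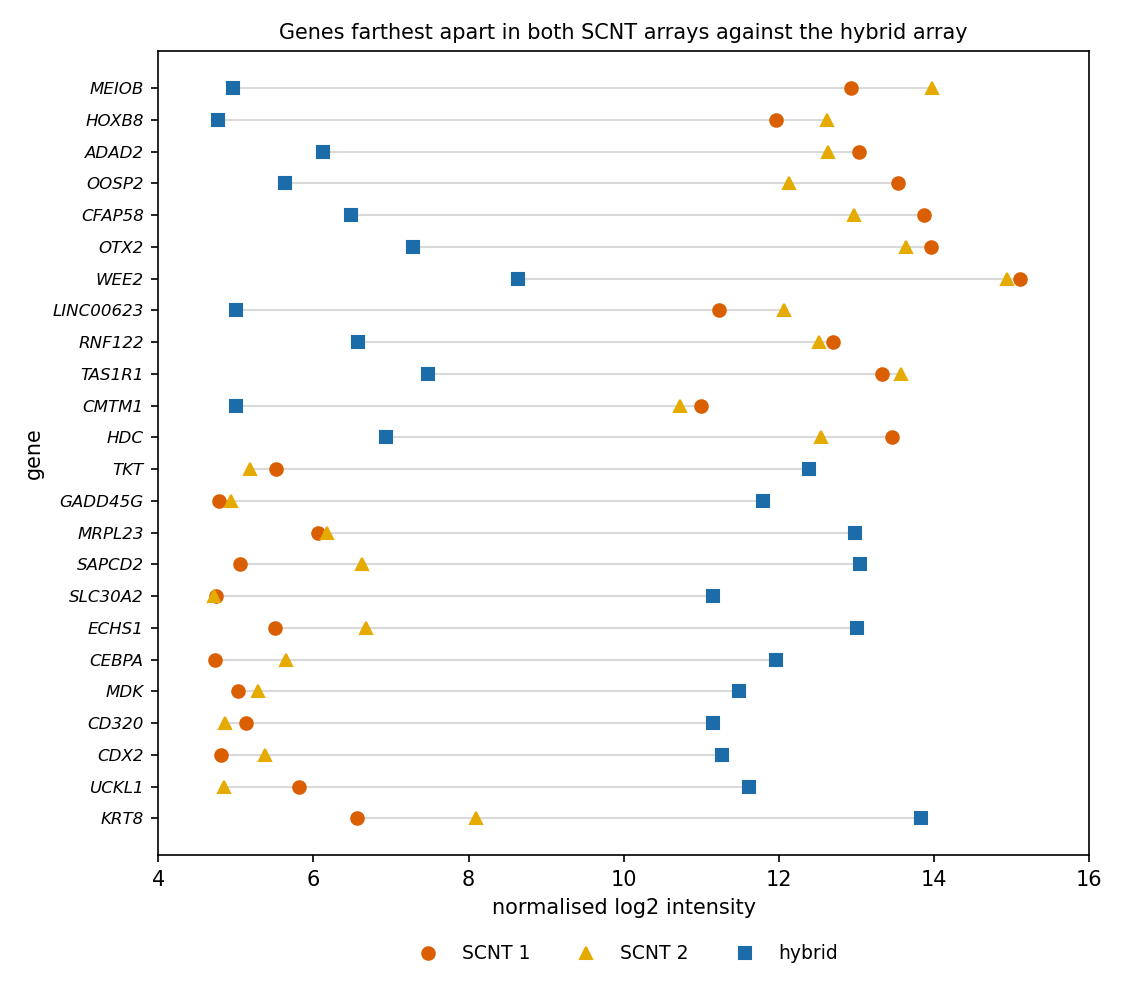
Normalised log2 intensity (x axis) on each array of the 12 genes farthest higher and the 12 farthest lower in both SCNT arrays against the hybrid array (y axis). The SCNT points lie close together for most of these genes, which were chosen by the smaller of both differences. All the lower genes except KRT8 were undetected on both SCNT arrays, so their SCNT points are background values. No gene shown passed the adjusted test.

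None of these 24 genes passed limma's test over all genes. At adjusted p under 0.05 limma called 0 of 9954 genes, with a smallest adjusted p of 0.388. At an unadjusted p under 0.05 it called 1206, of which 489 were higher and 717 lower in SCNT, against 497.7 expected by chance. By size alone, 1544 genes were at least 2-fold higher on each SCNT array and 2019 at least 2-fold lower. Of the higher genes, 369 were not detected on the hybrid array. Of the lower genes, 1161 were not detected on either SCNT array, and for 359 of those the bound itself reached 2-fold. In simulated data of the same 3-array design, with 200 single genes changed per run, limma called 0 of 1369 genes changed by 6 (log2). Adjusted calls depend on the share of genes changed, which may be larger in the real data. The simulation therefore does not settle why 0 genes were called. With only the genes detected on all 3 arrays, a filter that drops genes undetected in SCNT, limma called 346 genes, 247 higher and 99 lower, and with median scaling the genes at least 2-fold apart split into 585 higher and 3803 lower.

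The SCNT arrays were closer to each other than to the hybrid array, though they also differed widely. Across genes, which are not independent replicates, Pearson's r was 0.809 (Spearman's rho 0.770) between SCNT 1 and SCNT 2, 0.670 (0.606) between SCNT 1 and the hybrid array and 0.715 (0.665) between SCNT 2 and the hybrid array. The SD of the log2 differences was 1.56, 1.98 and 1.86 in the same order. Between the SCNT arrays 4298 genes were at least 2-fold apart, among them ZFP42, at 5.00 on SCNT 1 and 9.43 on SCNT 2, and TFCP2L1, at 5.14 and 10.43. Setting SCNT 1 against the other arrays left 2169 genes at least 2-fold apart from both, and setting SCNT 2 against the others left 2015, compared with 3563 for the hybrid array. Of the 9056 genes detected on the hybrid array 2436 were detected on neither SCNT array, and of the 4988 detected on both SCNT arrays 176 were not detected on the hybrid array. The lowest signal among detected probes, after normalization, was lower on the hybrid array than on either SCNT array. A gene at the same level on all arrays could thus be detected on the hybrid array and missed on both others. The detection counts therefore do not by themselves show that a gene differed in expression.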

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

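The tests of scaling, of unscaled signal, of fibroblast genes and of other splits below were chosen after the results they address were seen, and the tests against genes of matched brightness were set before, with the median at the bounds added after.

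Probes without a gene name in the annotation used here gave signal that no comparison above reports. Of 1389 such probes, 530 (38.2%) were detected on at least 1 array, against 41.3 expected if none had signal and 44.1% of named probes. By array, 336 were detected on SCNT 1, 295 on SCNT 2 and 484 on the hybrid array.

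The contrast between higher oocyte maternal genes and lower trophectoderm and oxidative phosphorylation genes on the SCNT arrays was weighed against less RNA and against the scaling. An equal loss of signal for all genes on the SCNT arrays would lower maternal genes too. On the unscaled signal, whose median over all genes was -1.72 (log2, SCNT minus hybrid), the maternal list's median was instead 2.19, 4.24 for SCNT 1 and 0.43 for SCNT 2. After 2 rounds of amplification the signal need not follow the RNA input. Whether less RNA raises the share of maternal transcripts was not tested and stays open. Random lists as bright on the hybrid array had medians no lower, at their 2.5 percentile, than -1.31 for the trophectoderm list and -0.90 for oxidative phosphorylation, against the observed -3.31 (-1.82 with undetected genes at their bound) and -1.32, so a loss that depends on brightness alone is argued against for these lists. Over the scalings and filters tried, the maternal median was never below 2.29 and the trophectoderm median never above -2.01. What also stays open is a difference between single samples, in stage, donor or scriptaid as much as in the oocyte genome, since the hybrid is 1 array.

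Fibroblast RNA on the hybrid array as a source of its keratin and trophectoderm signal was also tested. It stays open, since the rule asked for all or none of 8 abundant fibroblast genes. Of these, 4 were detected on that array (SPARC, VIM, LGALS1 and TIMP1), at log2 levels from 7.12 (TIMP1) to 8.73 (VIM). The other 4 were not (COL1A1, COL1A2, COL3A1 and FN1). TIMP1 was also detected on both SCNT arrays. The 7 trophectoderm genes at least 2-fold lower on each SCNT array lay at 8.68 (KRT7) to 13.83 (KRT8) on the hybrid array. ANXA2 and S100A6, of the fibroblast list, were detected there too, at log2 levels of 14.16 and 10.85. Both are expressed by other cell types as well. Other epithelial cells were not tested.

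The count of genes at least 2-fold apart was 3563 with the hybrid array set against the others, and the highest count of the other splits was 2169. The design has 3 splits, and in 1 of them, the real one, the count was as large, too few for a share under 0.05.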

How the results depend on the processing

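The scaling to probes detected on all 3 arrays was chosen after seeing the data, and every other alternative was fixed before. The maternal, trophectoderm and oxidative phosphorylation lists kept their direction and their call under each other background, scaling, filter and probe choice that gave a value. The trophectoderm list had too few genes detected on all 3 arrays for one. They lost the call, at 3.33, -3.31 and -1.32, with an estimated correlation (adjusted p = 0.924 for each), where 0 lists passed instead of 3. With fry, which asks whether a list moves at all and not whether it differs from other genes, they gave adjusted p of 0.417, 0.182 and 0.251, and 0 lists passed. Without a filter 5 lists passed, heat shock and stress (adjusted p = 0.000746) and housekeeping (0.0343) among them. The stress list also passed with normexp (0.0232), without background correction (0.0472), with genes detected on all 3 arrays (0.00824, as did housekeeping), with the looser filter (0.0146) and with the mean of probes (0.0422).

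The count of genes called by limma was 0 under each alternative except 2. It was 346 with genes detected on all 3 arrays and 349 after scaling to commonly detected probes (170 higher, 179 lower), where the prior degrees of freedom, estimated from 1 residual degree, went from 2.59 to 20.8 and to infinity. The count moved with that estimate.

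The balance of genes at least 2-fold apart moved with the normalization: 43.3% were higher in the main setting, 13.3% with median scaling (585 higher, 3803 lower) and 24.5% with the authors' scaled values (3316 lower), which change background correction and floor too, where the median of all genes was -1.0 and -0.74 instead of -0.08. With genes detected on all 3 arrays there were 1648 in all, 529 of them lower, 67.9% were higher, and the median was 0.36. With 1 SCNT array left out, which asks for a single pair to differ, the count ranged from 5497 to 5800, with 2403 to 2629 higher and 3094 to 3171 lower, and the trophectoderm median from -3.87 to -3.59, the maternal one from 2.38 to 4.70 and the oxidative phosphorylation one from -1.40 to -1.20. Uncalled lists also turned sign there: cell cycle (0.10), imprinted (0.22) and genome activation (-0.41) without SCNT 1, and ribosome biogenesis (0.20) and cumulus (-0.58) without SCNT 2. Of the named genes, 22 moved by more than the SD of the SCNT arrays without SCNT 1 and 28 without SCNT 2, 0 of them with a turned sign. PHLDA2 and NANOG, with a wide SD, turned sign without SCNT 1. No test remains in that case. No paired analysis was possible because the groups share no sample number. The excess of the correlation between SCNT arrays over the mean of the other pairs was 0.116, 0.0531 without a filter and 0.149 with genes detected on all 3 arrays.

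Medians of lists without a call turned sign 18 times, and 10 of these kept their side of the median of all genes in the same setting. With median scaling genome activation (-0.63), cumulus (-0.67) and p53 (-0.32) stayed above all genes (-1.0), as did genome activation (-0.50) and cumulus (-0.23) with the authors' values (all genes -0.74), cumulus without background correction (-0.12, all genes -0.16), and imprinted without a filter (0.10, all genes 0.094) and with genes detected on all 3 arrays (1.07, all genes 0.36). Chromatin modifier with the latter (0.33) and blood with the looser filter (0.036, all genes 0.12) stayed below. The 8 others turned against all genes too: cumulus with normexp (-0.047) and the looser filter (-0.41), genome activation with the mean of probes (-0.17), fibroblast (0.14), blood (0.23) and interferon (0.15) without a filter, and cell cycle (0.071) and splicing (0.026) with scaling to common probes. Signal over background limits the genes undetected on the SCNT arrays, whose differences are bounds.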

Other observations

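The split of the imprinted genes by parental allele, its permutation test and the comparison of background corrections were chosen after the values were seen. The comparison with genes of matched brightness was set before its result, and asking it of the median at the bounds as well was added after.

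The detected imprinted genes were divided by the parental allele they are known to be expressed from. Of the 6 maternally expressed genes (H19, MEG3, CDKN1C, PHLDA2, GRB10 and UBE3A), 3 were at least 2-fold lower on each SCNT array and 0 at least 2-fold higher, with a median log2 difference of -2.74, or -1.88 with undetected genes at their bound. Of the 6 paternally expressed genes (MAGEL2, KCNQ1OT1, NDN, PEG3, SNRPN and MKRN3), 1 was at least 2-fold higher, MAGEL2, and 0 at least 2-fold lower, with a median of 0.49. In these classes 5 and 4 genes were undetected on at least 1 SCNT array, so both medians rest partly on background. PHLDA2 differed by 0.23 on SCNT 2 and was not detected on SCNT 1. UBE3A, whose imprinting is known from neurons, differed by -0.02, and GRB10, whose imprinting depends on the tissue, was not detected on SCNT 1 and differed by -0.81 on SCNT 2. INPP5F was left out of the classes because a variant transcript of it, which its probe was not matched to, is the imprinted one.

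A candidate explanation, which these data do not test, is that the oocyte genome kept in the hybrid, which carries maternal imprints, supplied these transcripts in addition to the maternal alleles of the somatic genome that both kinds of sample hold. An exact permutation of the allele classes over the 12 genes gave p = 0.0130 (two-sided, 924 assignments), which restates the split seen, since the classes were set after the values and genes on 3 arrays are not replicates. Brightness on the hybrid array alone stays open, since random lists matched on it had a 2.5 percentile of -2.09, which the fitted median passes and the median at the bounds does not. Over the background corrections tried and the authors' values, which leave out the quantile step, the difference between the class medians was -2.04 or lower, with undetected genes at their fitted values. H19, CDKN1C and PHLDA2 are also trophoblast genes, so a hybrid with more trophectoderm transcripts stays open, as does a difference between single samples.

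GATA3, a trophectoderm transcription factor gene named after its values were seen, was at 10.16 on SCNT 2 and 11.11 on the hybrid array and was not detected on SCNT 1. LIN28B, chosen in the same way, was at 10.91 on SCNT 2 and 6.47 on the hybrid array and was not detected on SCNT 1.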
